A study of Mus musculus with 491 samples.

How the data were processed

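Single cells were sorted by tdTomato fluorescence from microdissected otic vesicles and periotic tissue of E10.5 mouse embryos that carried Pax2-Cre and the Ai14 reporter. In these embryos, cells that have expressed Cre from the Pax2 transgene, and their descendants, are red fluorescent. Per the labels' protocols, each cell was lysed in a well of a 96-well plate, cDNA was made with the SMARTer Ultra Low Input RNA kit V3, libraries were made with the Nextera XT kit, and paired-end reads were sequenced on an Illumina HiSeq instrument. Each of the 491 samples is 1 cell. The sample titles give 2 replicates, with 237 cells of replicate 1 on plates 1 to 3 and 254 cells of replicate 2 on plates 4 to 6. Whether a replicate stands for an embryo, a litter or a sorting day is not given in the sources used here.

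The deposited table holds 1 column per cell and 19659 rows with Ensembl gene identifiers. Per the submitters' processing notes, FastQC, cutadapt, Bowtie, Bowtie2, TopHat, SAMtools and Cufflinks were used with genome build mm10, and the notes give no versions. The deposited values are read here as log2(FPKM + 1), where FPKM is the fragment count scaled to transcript length and library size. The name of the table gives FPKM, and the log scale was worked out from the values: after raising 2 to each value and subtracting 1, 99.75% of the values above 0 were numbers of 6 significant digits to within a relative error of 1e-07. No read counts were used here, so the depth of a cell in reads is unknown. The sum of FPKM over genes ranged from 148501 to 439456 per cell (median 314943), and 2552 to 6403 genes per cell (median 4513) had an FPKM of at least 1. Of all values, 74.9% were listed at 0.

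Gene symbols and coordinates came from the GENCODE M21 annotation of GRCm38, the assembly that mm10 names, matched on the identifier for 19630 of 19659 rows, and 29 rows had no match. The 132 rows of 63 identifiers that occurred more than once were left out, among them those of Ntrk3 and Aldh1a1, as were 33 rows with no symbol or a symbol shared with another identifier. This left 19494 genes. Map1b, Map2, Eno1, Pkm and the listed genes with a hyphen in the symbol had no usable row. All 491 cells passed the minimum of 2000 genes with an FPKM of at least 1.

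Cell classes were made from 89 marker genes in 13 lists: otic epithelium, early neuroblast, differentiating neuron, epibranchial neuron, mesenchyme, neural crest or glial precursor, endothelium, erythroid cell, macrophage, neural tube progenitor, surface ectoderm, pharyngeal endoderm and head muscle progenitor. The 69 markers found in at least 1% of cells were centred, scaled to unit variance and clipped at 10, and reduced to 15 principal components. A graph of 15 nearest neighbours was clustered by the Leiden algorithm at resolution 1.0 with a fixed seed. The 11 clusters were named from their leading genes and markers, each name ending in "-like" because no label gives a cell type, and clusters 5 and 7, whose markers fell between lists, kept their numbers. The lists, comparisons, tests, the rule for named genes and the settings named as alternatives, other than those said to have been chosen after seeing the data, were fixed before the data were examined. Fry, a test of gene lists explained below, and the adjustment of p-values over the genes of a single list were not fixed then.

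Cells are not replicates of a class, so the log2(FPKM + 1) values were averaged per class and replicate, and these 16 means (8 classes with at least 5 cells in each replicate) were fitted with limma, with the class and the replicate as terms and with a trend in the empirical Bayes step. The replicate stood in the model as a block, and the closing section gives the counts without it, for example 541 in place of 579 genes between early neuroblast-like and otic epithelium-like cells. Genes with an FPKM of at least 1 in at least 5% of cells were tested, 10168 in all, after the 82 marker genes with a row had been left out because they define the classes. A gene was called at a Benjamini-Hochberg adjusted p below 0.05, and a standard error (SE) stands beside each difference given in full. Comparisons were early neuroblast-like minus otic epithelium-like, differentiating neuron-like minus early neuroblast-like, differentiating neuron-like minus otic epithelium-like, and mesenchyme-like minus otic epithelium-like. Genes higher in early neuroblast-like cells than in both neighbours were those called in both contrasts, and each further class was compared with otic epithelium-like cells in the same fit. The comparison of cluster 7 with differentiating neuron-like cells was added after seeing the data.

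Gene lists were tested with camera of limma, two-sided, at a preset correlation between genes of 0.01 and again with an estimated correlation, with adjustment over the lists of a comparison, and with fry, which tests whether a list's genes move, on balance, one way. The 21 lists were Notch pathway, epithelial junctions and keratins, epithelial-mesenchymal transition, basement membrane, neuronal migration, neuronal cytoskeleton, axon guidance and adhesion, neurotrophin and GDNF receptors and ligands, synaptic vesicle and secretion, G1/S and DNA replication, G2/M and mitosis, cell cycle exit, FGF pathway, BMP pathway, Wnt pathway, Hedgehog pathway, retinoic acid pathway, otic patterning and sensory competence, Hox genes, immediate early and heat shock, and glycolysis. Named genes are the 6 with the largest positive and the 6 with the largest negative difference among those called with the same sign in both replicates, the 2 to 4 members with the smallest adjusted p of each list with at least 3 called members, and the member with the smallest adjusted p of any other list described. For genes highest in early neuroblast-like cells they are the 10 with the largest smaller difference. Some genes that the rule takes are not reported here. Intervals of cell shares are exact Clopper-Pearson 95% intervals and cover counting error only.

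Transfer between wells was looked for after the most alike cells were seen to sit in neighbouring wells. For each ordered pair of wells in 1 column position of a replicate, the median ratio of the receiving to the source FPKM was taken over genes found in at most 10% of cells and at an FPKM of at least 50 in the source, with at least 5 such genes. Pairs of row positions with a median above 1% of the source in both replicates were taken as linked. In corrected values the estimated share of the source was taken off the receiving cell, values up to 3 times that share were set to 0, and 5 cells with an estimated share above 0.5 of the source were left out. The counts of genes or cells in the closing section that test an explanation used 100000 permutations of cells within replicates, or Fisher's exact test.

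The fit was tested on simulated data. Between pseudo-classes of 8 cells per replicate drawn from otic epithelium-like cells (10074 genes, 20 draws), with no change, 0.15 genes were called on average and 1 at most. These pseudo-classes were drawn at random, whereas the real classes were clustered from marker genes in the same cells. Genes that vary with the markers differ between such classes by construction, and the simulation does not cover calls of that kind. With 200 genes changed, none was called with the wrong sign, 9.5% of the calls were unchanged genes, and 0.8%, 7.9% and 21.6% of genes changed 2-fold, 4-fold and 8-fold with a mean log2 value of at least 2 were recovered. Preset camera called 1.25 of 20 lists per unchanged comparison and estimated camera called 0, and a list of 30 genes shifted 2-fold was called in 14 and 3 of the 20 draws. With known changes added to unchanged genes in the cells of the comparison of early neuroblast-like with otic epithelium-like cells (10168 genes, 20 draws), 15.8%, 41.2% and 74.2% of genes changed 2-fold, 4-fold and 8-fold were recovered at a mean log2 value of at least 2, and 57.1%, 96.1% and 100% at a mean of at least 5. The median estimates for known log2 changes of 1, 2 and 3 were 0.79, 1.48 and 2.15 in the first set. The unchanged genes were picked for a high p in this same contrast, so their observed differences, noise included, were small. These shares and estimates may thus not describe a typical gene. The transfer estimate returned 1.0%, 3.0% and 10.0% of the source where those shares had been added (10527 genes, 200 pairs). The shares were added as exact fractions of the source FPKM, so this follows nearly by construction. It does not test the estimate under sampling noise, nor the step that sets low values to 0.

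Alternatives were a pseudocount of 0.1, the log2 of the mean FPKM over cells, no filter on low values or a filter at 20% of cells, no replicate block, means per class and plate, upper-quartile scaling of each cell, weights by number of cells, clustering on the 2000 most variable genes, Leiden resolutions of 0.5 and 2.0, a minimum of 4000 genes per cell, and leaving out each replicate. Added after seeing the data were values corrected for transfer, with the classes kept or clustered again, cells without a source well alone, clusters 5 and 7 pooled with the neurons, and leaving out 7 cells with endothelial or macrophage markers. The work used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scikit-learn 1.9.0, scipy 1.17.1, python-igraph 0.11.9, leidenalg 0.10.2 and matplotlib 3.10.9, and R 4.3.3 with limma 3.58.1.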

Results

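The data are gene expression values of 491 single cells that were sorted as tdTomato-positive from the otic vesicle and the periotic tissue around it, at the stage when neuroblasts leave the otic epithelium to form the ganglion of the inner ear. Replicate 1 holds 237 cells, on plates of 77, 82 and 78 cells, and replicate 2 holds 254 cells, on plates of 84, 86 and 84 cells. Depth in reads is unknown. The sum of FPKM had a median of 310969 per cell in replicate 1 and 323096 in replicate 2, and the number of genes with an FPKM of at least 1 had medians of 4471 and 4572.

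The marker genes split the cells into 9 classes, and both replicates held each of them. Otic epithelium-like cells made up 27.7% of the cells (136), with 28.7% of replicate 1 (95% interval 23.0 to 34.9) and 26.8% of replicate 2 (21.4 to 32.7). Early neuroblast-like cells made up 8.4% (41), with 5.9% (3.3 to 9.7) and 11% (7.1 to 15.1). Differentiating neuron-like cells numbered 50, with 9.3% (5.9 to 13.7) and 11% (7.5 to 15.5). Neural tube progenitor-like cells made up 20.8% (102), with 23.6% (18.4 to 29.6) and 18.1% (13.6 to 23.4). Surface ectoderm-like cells were 9.0% (44), with 8.0% (4.9 to 12) and 9.8% (6.5 to 14.2), and mesenchyme-like cells 4.7% (23), with 6.3% (3.6 to 10) and 3.1% (1.4 to 6.1). Cluster 7, with the epibranchial neuron markers Phox2a and Tlx3, held 9.0% (44), with 8.4% (5.2 to 12.7) and 9.4% (6.1 to 13.7), and cluster 5, with neuronal and neural tube markers together in the deposited values, 9.2% (45), with 8.0% (19 of 237, 4.9 to 12) and 26 of 254 cells (6.8 to 14.6). Neural crest or glial precursor-like cells were 1.2% (6), too few to be tested, with 1.7% (0.5 to 4.3) and 0.8% (0.1 to 2.8). For each class the intervals of the replicates overlapped.

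**Figure D1:**
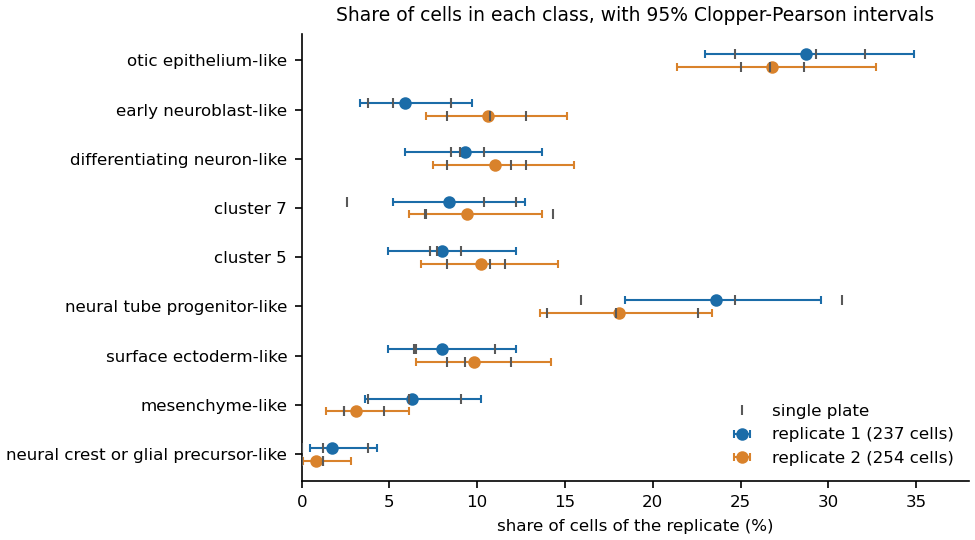
Share of cells (%) in each of the 9 classes in replicate 1 and replicate 2. Points are replicates with 95% Clopper-Pearson intervals and ticks are single plates, and otic epithelium-like cells range from 24.7% to 32.1% of a plate.

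Among the class-defining genes, the otic genes Oc90, Lmx1a and Dlx5 were found at an FPKM of at least 1 in 58.1%, 69.9% and 70.6% of otic epithelium-like cells, and the cell adhesion gene Epcam in 100%. Neurog1, the proneural factor that starts the otic neuronal lineage, was found in 48.8% of early neuroblast-like cells, 2.9% of otic epithelium-like cells and 14.0% of neuron-like cells. Its target Neurod1 was found in 95.1% of early neuroblast-like and 100% of neuron-like cells, and the neuronal genes Stmn2 and Pou4f1 in 24.4% and 26.8% of early neuroblast-like and 100% and 98.0% of neuron-like cells. Pax2 itself was found in 15.4% of otic epithelium-like cells. The neural crest genes Sox10 and Erbb3 were also found in 85.3% and 56.6% of otic epithelium-like cells. Cells of other types sat inside some classes: 3 early neuroblast-like cells of replicate 2 held 6 to 7 of 7 endothelial markers, and 3 neural tube progenitor-like cells and 1 otic epithelium-like cell of replicate 1 held 6 of 6 macrophage markers. No cell held at least 3 markers of head muscle or of pharyngeal endoderm.

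**Figure D2:**
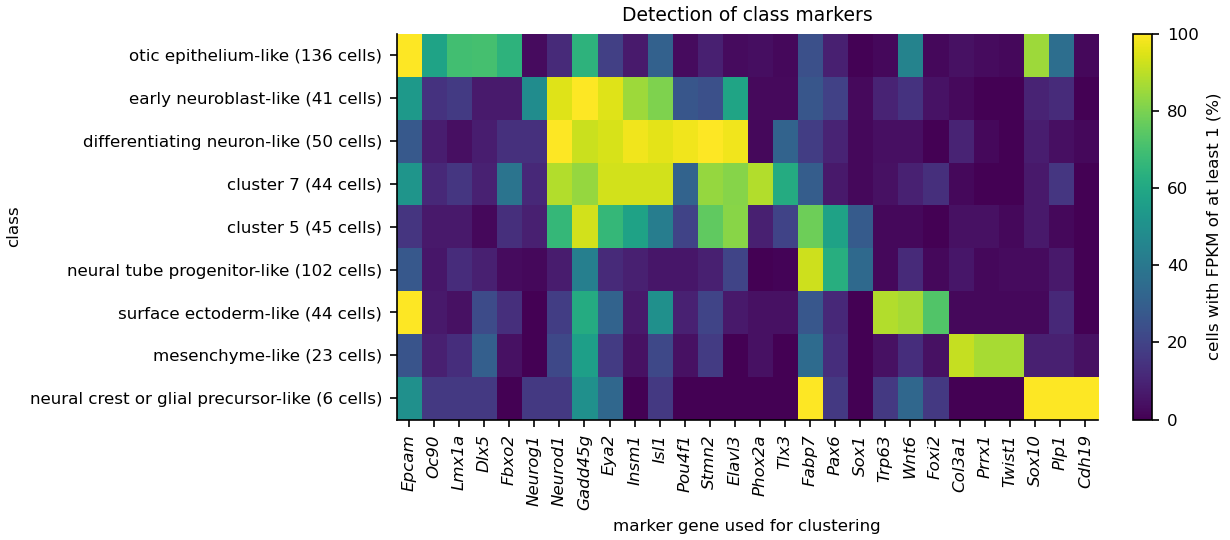
Percentage of cells (colour scale, 0 to 100%) with an FPKM of at least 1 for 28 class-defining genes (columns) in the 9 classes (rows). Phox2a stands at 88.6% in cluster 7 and 2.0% in differentiating neuron-like cells.

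Transcripts were shared between wells, which bears on the share of cells in which a gene is found. At the same column position, 19 pairs of row positions shared rare transcripts in both replicates, and 17 of them were neighbouring rows of 1 plate. In the linked wells the receiving cell held a median of 4.1% of the source (quartiles 2.6 and 7.1). A source well was present for 337 cells and absent for 154. Xist, transcribed in female cells, and a Y-linked transcript occurred together in 15.7% of the cells with a source well (53 of 337, 95% interval 12 to 20.1) and in 0.6% of those without (1 of 154, 0.0 to 3.6). After the correction they occurred together in 0.2% of cells (1 of 486, 0.0 to 1.1). Cells with neither went from 74 of 491 as deposited to 95 of 486, so the correction may also remove a cell's own transcripts. Epcam was found in 53.7% of early neuroblast-like cells as deposited (37.4 to 69.3) and 34.1% after the correction (20.1 to 50.6). In neural tube progenitor-like cells, which should lack it, the shares were 27.5% and 3.0%. Stmn2 went from 10 to 5 and Pou4f1 from 11 to 8 of 41 early neuroblast-like cells, while Neurog1 stayed at 48.8%. In cluster 5, where 8 of 45 cells lacked a source well, Neurod1 went from 66.7% to 20.5%, Isl1 from 42.2% to 2.3% and Stmn2 from 75.6% to 47.7%. The correction sets low values to 0 whether they were transferred or the cell's own, so these falls follow in part by construction. As deposited, the 8 cells of cluster 5 without a source well held Neurod1 in 1, Isl1 in 0 and Stmn2 in 5 cells. Transfer may thus account for part of the Neurod1 and Isl1 found in cluster 5. These 8 cells are too few to size that part, and Stmn2 was found in most of them.

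**Figure D3:**
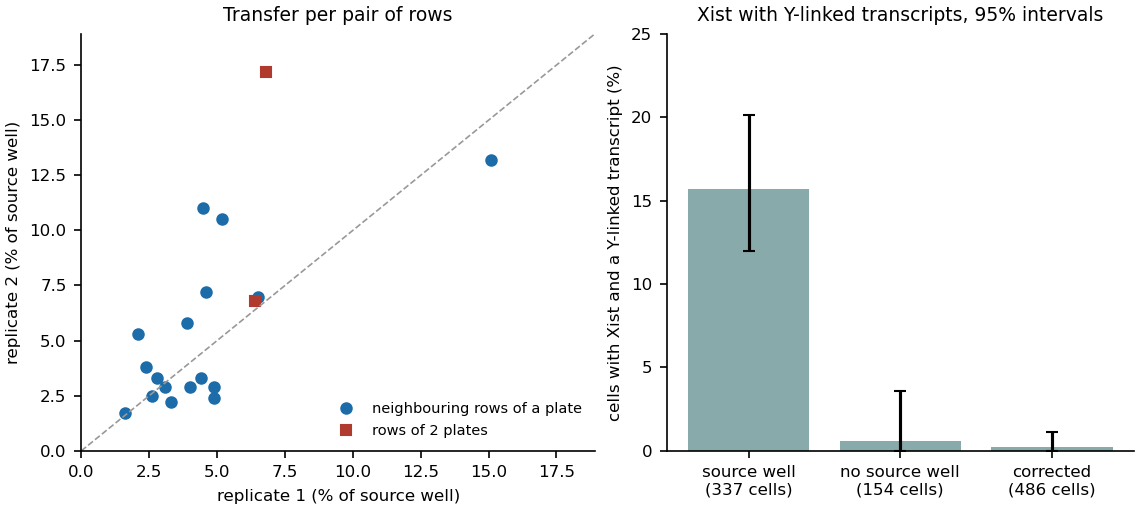
Left, transfer between row positions (% of the source well) in replicate 1 and replicate 2, with a point per ordered pair of row positions. Right, percentage of cells with both Xist and a Y-linked transcript, with 95% Clopper-Pearson intervals, which is 15.7% with a source well, 0.6% without one and 0.2% after the correction.

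The comparison of early neuroblast-like with otic epithelium-like cells asks what changes as neuroblasts arise in and leave the epithelium. It presumes that the early neuroblast-like cells come from the otic epithelium, and their origin was not tested. Epithelial junction and keratin genes were lower as a group in early neuroblast-like cells, and the Notch ligands Dll1 and Dll3 were higher. The keratin gene Krt18 (ENSMUSG00000023043, chromosome 15, 102028180 to 102032027) had a log2 difference of -5.36 (SE 0.62, n = 2 replicates, adjusted p = 1.97e-05), with -4.52 and -6.20 in the replicates. The tight junction gene Cldn6 (ENSMUSG00000023906, chromosome 17, 23679249 to 23682446) differed by -5.29 (SE 0.48, n = 2, adjusted p = 1.83e-06). Id3 (ENSMUSG00000007872, chromosome 4, 136143497 to 136145755), an inhibitor of proneural factors, differed by -4.71 (SE 0.36, n = 2, adjusted p = 1.82e-07). Ppp1r14a (ENSMUSG00000037166, chromosome 7, 29289308 to 29293801), an inhibitor of protein phosphatase 1, was higher by 6.08 (SE 0.41, n = 2, adjusted p = 5.37e-08). Hes6 (ENSMUSG00000067071, chromosome 1, 91411483 to 91414038), which promotes neuronal differentiation, was higher by 4.57 (SE 0.33, n = 2, adjusted p = 1.05e-07).

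Of 10168 tested genes, 579 differed, 152 higher and 427 lower in early neuroblast-like cells. These cells held a median of 4311 genes with an FPKM of at least 1, against 4786 in otic epithelium-like cells. The median difference over all tested genes was -0.147. The share of higher genes was 26.3%, against 38.4% with the log2 of the mean FPKM and 21.7% with upper-quartile scaling. Whether the lower number of genes found accounts for the excess of lower genes was not tested. The other largest increases were Btbd17 (5.33), Spsb4 (4.32), Mfap4 (4.31) and the actin-binding Cotl1 (4.26). The other largest decreases were the claudin Cldn7 (-5.08), the carbonic anhydrase Car2 (-4.40) and the growth factor Ptn (-4.05). Here and below, each value in parentheses after a gene is a log2 difference with an adjusted p below the threshold and the same sign in 2 of 2 replicates, and in 6 of 6 plates unless another number is given. For genes said to have been chosen after their values were seen, plates were not counted. A p in parentheses after a gene list is that of camera, adjusted over the lists. The classes were made from markers in the same cells, so genes that vary with those markers are expected to differ. The p-values do not allow for this.

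Of the 30 epithelial junction and keratin genes, 17 fell and none rose (25 and 0 adjusted over the list alone; camera adjusted p = 6.42e-24, median -1.44). Among them were Ap1m2 (-4.04), which sorts proteins in polarised cells, and Krt8 (-3.84). Of 17 basement membrane genes 5 fell (7 adjusted over the list alone; camera adjusted p = 4.1e-05), namely Col18a1 (-2.81), Itga6 (-1.57), Fras1 (-1.37), Frem2 (-1.0) and, chosen after its values were seen, Col4a1 (-1.77). The epithelial-mesenchymal transition genes did not move as a group (camera adjusted p = 0.117, median -0.12, mean 0.07, test upward). The transcriptional repressors Zeb1 (3.29), Snai2 (1.32) and, chosen after its values were seen, Zeb2 (1.77) rose, while Sox9 (-2.73) and the matrix gene Sparc (-2.24) fell. Adjusted over the list alone, 4 of these 14 genes rose and 2 fell.

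Signalling and synaptic groups also differed. Of 17 Notch pathway genes 5 rose and 1 fell (8 and 2 adjusted over the list alone; camera adjusted p = 6.75e-07). They were the ligands Dll1 (2.41) and Dll3 (3.52), the Fringe glycosyltransferase Mfng (3.4) and Hes6, and, chosen after their values were seen, Hes5 (2.19) and Jag1 (-1.78). Of 15 BMP pathway genes 8 fell and none rose (11 adjusted over the list alone; camera adjusted p = 9.57e-10), with the BMP targets Id2 (-3.30) and Id4 (-2.91) and the decoy receptor Bambi (-2.79). Of 12 retinoic acid pathway genes 4 fell (5 adjusted over the list alone; camera adjusted p = 0.000318). Among these were the retinoid enzymes Rdh10 (-1.81) and Aldh1a3 (-0.62, 5 of 6 plates) and the binding protein gene Crabp2 (-1.30). Of 14 synaptic vesicle genes 2 rose (6 adjusted over the list alone; camera adjusted p = 1.41e-05), Syp (1.72), a synaptic vesicle protein, and, chosen after its values were seen, Cplx2 (1.01). These groups and the epithelial and basement membrane genes also passed with an estimated correlation, with adjusted p from 0.00874 to 0.0197.

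Further groups passed with the preset correlation alone. Of 19 neuronal cytoskeleton genes 4 rose (9 adjusted over the list alone; camera adjusted p = 4.17e-10), Dpysl4 (2.91), the growth cone gene Basp1 (2.77), Mllt11 (2.22) and the neurofilament gene Nefm (1.99), with adjusted p = 0.084 with an estimated correlation. Of 7 neurotrophin and GDNF receptor and ligand genes 3 rose (4 up and 1 down adjusted over the list alone; camera adjusted p = 0.00234; adjusted p = 0.0863 with an estimated correlation), with the GDNF co-receptor Gfra1 (2.34) and the neurotrophin Bdnf (1.39). Of 19 Wnt pathway genes 3 fell (7 adjusted over the list alone; camera adjusted p = 0.0014; adjusted p = 0.0892 with an estimated correlation), Tcf7 (-1.67), Wnt7b (-1.65) and Sp5 (-0.76). Of 21 otic patterning genes 4 fell and 1 rose (6 and 1 adjusted over the list alone; camera adjusted p = 0.00785; adjusted p = 0.084 with an estimated correlation). Those that fell were the transcription factors Tbx2 (-2.90), Gbx2 (-2.57), Tbx1 (-2.11) and Gata2 (-1.15, 5 of 6 plates). Among 9 cell cycle exit genes 1 rose, also adjusted over the list alone (camera adjusted p = 0.0435; adjusted p = 0.0952 with an estimated correlation), the antiproliferative Btg2 (2.6, 5 of 6 plates). Of 5 Hox genes none passed, also adjusted over the list alone, though camera called the list upward (adjusted p = 0.0437; adjusted p = 0.145 with an estimated correlation), and Hoxb2 had a value of 0.82 (adjusted p = 0.443, 5 of 6 plates).

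The remaining groups did not pass as groups. Of 17 FGF pathway genes 3 rose and 3 fell (3 and 6 adjusted over the list alone; camera adjusted p = 0.695, median -0.20, mean -0.17, test upward). The ligands Fgf10 (2.61), Fgf8 (1.88, 5 of 6 plates) and Fgf15 (0.95, 4 of 6 plates) rose, and Fgf9 (-2.0) and, chosen after their values were seen, Fgfr2 (-1.89) and Il17rd (-0.73) fell. No gene of the 24 for G1/S and DNA replication passed, also adjusted over the list alone (camera adjusted p = 0.557, median -0.25, mean -0.09, test upward; E2f8 1.13, adjusted p = 0.192, 6 of 6 plates). None passed of the 24 for G2/M (0.0911; Bub1b -1.43, adjusted p = 0.0595, 5 of 6 plates) or the 17 for neuronal migration (0.0951; Astn1 0.72, adjusted p = 0.193, 5 of 6 plates). One gene each fell, also adjusted over the list alone, among 24 axon guidance genes (0.299, median 0.03, mean -0.06, test upward; Epha4 -1.65), 8 Hedgehog genes (0.558; the co-receptor Cdon -0.97) and 14 glycolysis genes (0.118; Gapdh -0.71). Of 13 immediate early and heat shock genes 2 fell (4 adjusted over the list alone; 0.062), Jun (-2.08) and, chosen after its values were seen, Fos (-1.73).

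**Figure D4:**
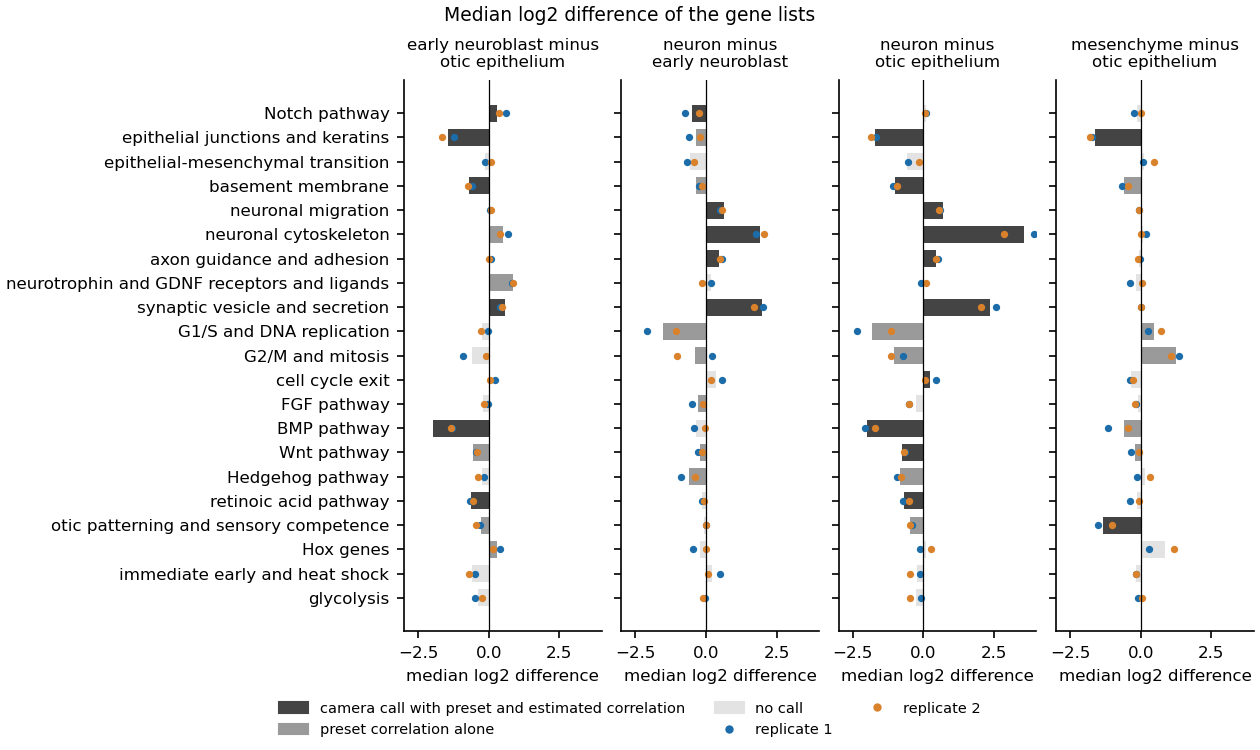
Median log2 difference of the 21 gene lists in the comparisons of early neuroblast-like with otic epithelium-like, neuron-like with early neuroblast-like, neuron-like with otic epithelium-like and mesenchyme-like with otic epithelium-like cells. Dots are replicates, dark bars mark camera calls with the preset and the estimated correlation, mid-grey bars calls with the preset alone and light bars lists with no call.

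In values corrected for transfer, 582 genes differed (126 of the 152 and 389 of the 427 among them), and the calls of Nefm (1.45, adjusted p = 0.154), Bdnf (1.25, 0.0686), Crabp2 (-1.85, 0.0502) and Gapdh (-1.09, 0.0676) ended, as did that of the cell cycle exit list (camera adjusted p = 0.05, at the threshold). Of 62 calls of named genes, 20 ended with the log2 of the mean FPKM, with Sparc at -0.97 (adjusted p = 0.765). In the 154 cells without a source well 28 of 61 ended, Dll1 (2.37, adjusted p = 0.0732) and Mfng (3.49, 0.0877) among them. The differences themselves held, with a median ratio of 1.03 to the values reported, so smaller differences did not end these calls as a set. The Hox list lost its call there and with fry. Bdnf (adjusted p = 0.0728) and Gapdh (0.0559) were called with the replicate block alone. Calls lost in at least 5 settings were those of Bdnf and Lrrn1 (7 each), Cdon, Fgf15, Gapdh and Nefm (5 each). The count ran from 145 in cells without a source well to 935 with classes weighted by their number of cells, and without the cells of endothelial or macrophage markers it was 601.

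The comparison of neuron-like with early neuroblast-like cells asks what changes as neuroblasts become neurons. Genes of the neuronal cytoskeleton and of synaptic vesicles rose as groups, and cyclin D1 fell. DNA replication genes fell as a group with the preset correlation alone (adjusted p = 0.0563 with an estimated correlation). Gap43 (ENSMUSG00000047261, chromosome 16, 42248442 to 42340651), a growth cone protein, was higher by 5.85 (SE 0.47, n = 2, adjusted p = 9.7e-07). The neurofilament gene Nefm (ENSMUSG00000022054, chromosome 14, 68082590 to 68124846) was higher by 5.22 (SE 0.53, n = 2, adjusted p = 9.95e-06) and the synaptic fusion gene Snap25 (ENSMUSG00000027273, chromosome 2, 136713453 to 136782428) by 4.52 (SE 0.43, n = 2, adjusted p = 5.36e-06). Ccnd1 (ENSMUSG00000070348, chromosome 7, 144929931 to 144939925), the gene of cyclin D1, differed by -3.29 (SE 0.41, n = 2, adjusted p = 6.75e-05). Prdm12 (ENSMUSG00000079466, chromosome 2, 31640037 to 31655795), a regulator of sensory neuron formation, differed by -3.04 (SE 0.38, n = 2, adjusted p = 7.45e-05).

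Of the 10168 genes 493 differed, 367 higher and 126 lower in neuron-like cells. The other largest increases were Rgs4 (5.3), a regulator of G protein signalling, Crmp1 (5.15), a mediator of axon guidance signals, and the neurofilament gene Nefl (4.21). The other largest decreases were Zfp36l1 (-3.04), an mRNA decay factor, the muscle-type enolase Eno3 (-3.03), the protease inhibitor Spint2 (-3.02) and Gsta4 (-2.94).

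Of 19 neuronal cytoskeleton genes 16 rose and none fell (18 adjusted over the list alone; camera adjusted p = 5.45e-25, median 1.91), with Tuba1a (1.52) beside Gap43, Crmp1 and Nefm. Of 14 synaptic vesicle genes 9 rose (10 adjusted over the list alone; 2.88e-15), with Syt11 (3.19), Syp (2.94) and Cplx1 (1.82). Of 17 neuronal migration genes 5 rose, also adjusted over the list alone (0.000201), with the microtubule-binding Dcx (3.77), Dclk1 (1.70), Sema6a (1.61), Cdk5r1 (1.55) and, chosen after its values were seen, Rnd3 (1.79). Of 24 axon guidance and adhesion genes 5 rose (9 adjusted over the list alone; 3.41e-05), with Ncam1 (2.22), the ephrin receptor Epha5 (1.92), the Slit receptor Robo2 (1.54), Cntn1 (1.12) and, chosen after its values were seen, L1cam (1.22). Of 17 Notch pathway genes 4 fell (1 up and 5 down adjusted over the list alone; 0.00198), Hes1 (-2.46), Dll1 (-2.24), Notch1 (-1.36) and Lfng (-0.70, 4 of 6 plates). These 5 groups also passed with an estimated correlation, with adjusted p from 0.00338 to 0.0424, but in cells without a source well the axon guidance list lost its call (0.138). Without the replicate block the call of Dclk1 ended (adjusted p = 0.0501).

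Of 24 genes of G1/S and DNA replication 11 fell and none rose (22 adjusted over the list alone; camera adjusted p = 3.4e-19; adjusted p = 0.0563 with an estimated correlation), with the replication genes Mcm3 (-2.61), Cdc6 (-2.27), Rrm2 (-2.15) and Gins2 (-2.08). No gene of the 24 for G2/M passed, also adjusted over the list alone (camera 0.0123, downward; adjusted p = 0.481 with an estimated correlation; Top2a -1.13, adjusted p = 0.147, 5 of 6 plates). The median of the G2/M list was 0.2 in replicate 1 and -1.02 in replicate 2, so the replicates differ in direction. Of 30 epithelial genes 2 fell (6 adjusted over the list alone; 0.00014; adjusted p = 0.0956 with an estimated correlation), Spint2 and, chosen after its values were seen, F11r (-1.66). In the basement membrane list 1 of 17 fell, also adjusted over the list alone (0.0123; adjusted p = 0.0573 with an estimated correlation), the collagen gene Col4a2 (-1.53). Of 17 FGF pathway genes 1 rose and 2 fell, also adjusted over the list alone (0.0296, downward; adjusted p = 0.144 with an estimated correlation), Fgf3 (1.26, 5 of 6 plates), Fgf8 (-1.29, 5 of 6) and Fgf15 (-1.16, 4 of 6). Camera also called the Hedgehog list (0.00198, downward; adjusted p = 0.0573 with an estimated correlation; Smo -1.50, adjusted p = 0.0549, 6 of 6 plates), in which 2 genes fell adjusted over the list alone and none over all genes. It called the Wnt list too (0.0212, downward; adjusted p = 0.197 with an estimated correlation; Fzd7 -0.55, adjusted p = 0.301, 4 of 6 plates), in which none passed, also adjusted over the list alone.

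The neurotrophin group did not pass (camera adjusted p = 0.328). In it 2 genes rose, with the receptor Ntrk2 (2.71), and the ligands Ntf3 (-1.67, 4 of 6 plates) and Bdnf (-1.45, 5 of 6) fell, also adjusted over the list alone. The epithelial-mesenchymal transition genes did not pass either (0.0538). Of these Zeb2 (1.94, 5 of 6 plates) and Vim (1.80) rose and Sox9 (-1.90), Snai2 (-1.16, 5 of 6) and, chosen after their values were seen, Sparc (-1.92) and Fn1 (-1.59) fell, also adjusted over the list alone. Cell cycle exit (0.112) held 2 genes that rose, also adjusted over the list alone, Gadd45a (2.15, 5 of 6 plates) and, chosen after its values were seen, Cdkn2d (2.03). Retinoic acid genes (0.14) had 1 up and 1 down, also adjusted over the list alone, Crabp2 (-2.64) and, chosen after its values were seen, Stra6 (2.12). One gene rose among otic patterning genes (list 0.389), and 1 among immediate early genes, Dusp1 (1.83; list 0.371). Adjusted over the list alone, 1 gene of the first rose, and 2 of the second rose and 1 fell. None passed among BMP (0.217; Chrdl1 0.74, adjusted p = 0.0605, 5 of 6 plates), Hox (0.217; Hoxb2 -0.75, adjusted p = 0.473, 5 of 6) and glycolysis genes (0.964, median 0.01, mean 0, test downward; Aldoa 0.51, adjusted p = 0.07, 6 of 6), with 1, 0 and 2 higher adjusted over the lists alone.

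In cells without a source well Dusp1 was -0.03, 37 of 50 calls of named genes ended (median ratio to the values reported 0.91), and the epithelial, basement membrane, axon guidance, G2/M and Wnt lists lost their calls. With fry the G2/M and Wnt lists lost their calls. With the log2 of the mean FPKM 16 of 52 calls of named genes ended, and 160 genes were higher and 138 lower, 53.7% higher against 74.4% in the values reported. The count ran from 39 in those cells to 1428 with cells clustered on the most variable genes, where 496 were higher and 932 lower, and Col4a2 lost its call in 11 settings, such as without the 3 cells of endothelial markers (-1.34, adjusted p = 0.104) and without the replicate block (0.0709). Other calls lost in at least 5 settings were those of Dclk1, Lrrn1 and Sema6a (7 each), Dusp1, Enc1, Gadd45a and Notch1 (6 each), and Vim and Zeb2 (5 each).

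**Figure D5:**
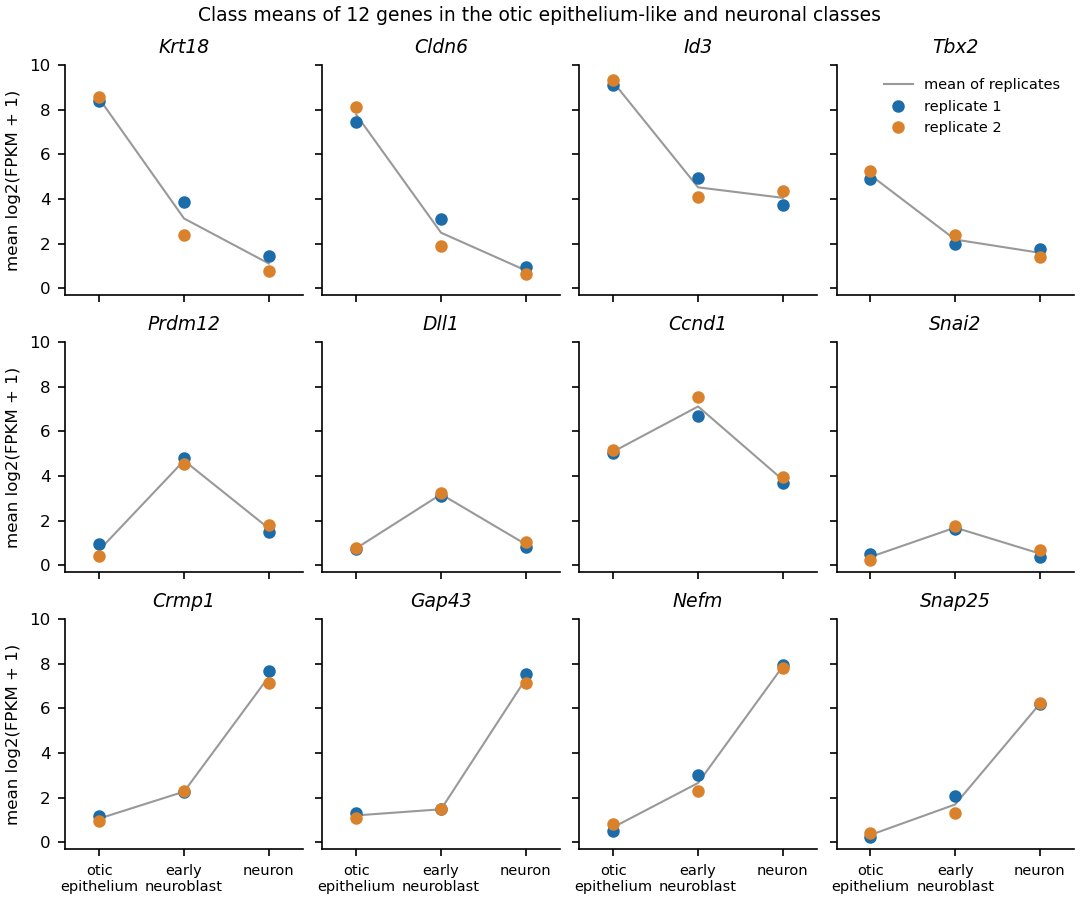
Mean log2(FPKM + 1) of 12 genes in otic epithelium-like, early neuroblast-like and neuron-like cells, with a point per replicate. Krt18, Cldn6, Id3 and Tbx2 are highest in the epithelium, Prdm12, Dll1, Ccnd1 and Snai2 in early neuroblast-like cells, and Crmp1, Gap43, Nefm and Snap25 in neuron-like cells.

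Genes higher in early neuroblast-like cells than in both neighbours were sought as candidate marks of the step at which neuroblasts are presumed to leave the epithelium. Prdm12 had means of 0.68, 4.70 and 1.65 log2(FPKM + 1) in otic epithelium-like, early neuroblast-like and neuron-like cells, a difference of 4.01 from the first and 3.04 from the last. It was also among the 10 leading genes of the 6 neural crest or glial precursor-like cells. The Notch ligand Dll1 (ENSMUSG00000014773, chromosome 17, 15367354 to 15376872) had means of 0.77, 3.18 and 0.94, and Ccnd1 had 5.1, 7.12 and 3.83. In all, 23 genes were higher than in both neighbours, each in 2 of 2 replicates, and those named here by the rule in at least 5 of 6 plates. The others with the largest smaller difference, given against the epithelium and against neuron-like cells, were Arl4a (2.62 and 2.92), Phldb2 (3.90 and 2.32), Vstm2b (2.35 and 2.04), Enc1 (1.75 and 1.77), Lrrn1 (1.52 and 1.66), Dlk2 (1.75 and 1.41) and Bdnf (1.39 and 1.45). Snai2, Fgf8 and Fgf15 from the lists were also among them. Both contrasts share the early neuroblast-like means: lists of these sizes shared 1.9 genes if independent, and a mean of 22.8 (highest 35) in 100 simulations of unchanged classes that share those means. The number of 23 was thus not above the highest of these simulations. The simulated classes held no effect and their lists were the top-ranked genes, so the overlap expected of classes that differ is not known. That no simulated gene passed both thresholds follows from the absence of effects and adds no support. With means per class and plate the calls of Snai2 ended (1.24, adjusted p = 0.0658, against the epithelium and -1.08, adjusted p = 0.137, in neuron-like minus early neuroblast-like cells). Those of Bdnf ended without the replicate block (adjusted p = 0.0728 and 0.0666). Those of Prdm12 ended with the log2 of the mean FPKM (-2.88, adjusted p = 0.159, in neuron-like minus early neuroblast-like cells), as did that of Fgf8 there (-0.94, 0.522). Those of Dll1 ended with clustering on the most variable genes (adjusted p = 0.275 and 0.193) and in cells without a source well. There Dll1 was 2.37 and -2.36 (adjusted p = 0.0732 and 0.116), and the calls of Ccnd1 ended too (2.76 and -2.95, adjusted p = 0.0837 and 0.103). Both calls were kept by Lrrn1 in 8 of 16 alternatives, Bdnf in 9 of 16, Enc1 in 10 of 16, Snai2 and Fgf15 in 10 of 15, and Vstm2b in 15 of 15, and the others lost a call in 1 or 2.

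The comparison of neuron-like with otic epithelium-like cells sets the ends of the presumed otic lineage side by side, and the origin of the neuron-like cells was not tested. Nefm was higher by 7.21 in neuron-like cells (SE 0.53, n = 2, adjusted p = 3.02e-08) and Ppp1r14a by 7.03 (SE 0.41, n = 2, adjusted p = 3.83e-09). Krt18 differed by -7.38 (SE 0.62, n = 2, adjusted p = 1.54e-07) and Cldn6 by -6.98 (SE 0.48, n = 2, adjusted p = 1.85e-08). Other large increases were Tagln3 (6.51), the neuronal transcription factor Ebf1 (6.41), Ppp1r17 (6.36) and Crmp1 (6.36), and other large decreases were Wfdc2 (-5.89), Gsta4 (-5.49), Krt8 (-5.33) and Cldn7 (-5.31). Of the 10168 genes 1449 differed, 580 higher and 869 lower.

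Neuronal groups rose. Of 19 neuronal cytoskeleton genes 18 rose, also adjusted over the list alone (camera adjusted p = 4.17e-28), with Gap43 (6.12) and Mllt11 (5.12). Of 14 synaptic genes 11 rose, also adjusted over the list alone (5.38e-17), with Snap25 (5.88), Syp (4.66), Scg3 (4.26) and Syt11 (3.72). Of 17 migration genes 3 rose (5 adjusted over the list alone; 2.8e-05), Dcx (5.01), Rnd3 (2.21) and Cdk5r1 (1.75). Of 24 axon guidance genes 6 rose (7 adjusted over the list alone; 5.31e-05), with Ncam1 (2.52), Robo2 (2.21), Epha5 (1.97) and Cntn1 (1.21). Of 9 cell cycle exit genes 4 rose, also adjusted over the list alone (0.00299), Gadd45a (2.47), Btg2 (2.34), Cdkn2d (2.02) and the retinoblastoma gene Rb1 (1.61).

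Epithelial and signalling groups fell. Of 30 epithelial genes 23 fell and 1 rose (25 and 1 adjusted over the list alone; camera adjusted p = 2.04e-20), the polarity gene Pard3 (1.77), chosen after its values were seen, being the exception. Of 17 basement membrane genes 8 fell (11 adjusted over the list alone; 1.71e-06), with Col18a1 (-4.18), Col4a1 (-2.76), Col4a2 (-2.47) and Fras1 (-1.53). Of 15 BMP genes 10 fell (12 adjusted over the list alone; 4.86e-08), with Id3 (-5.18), Id2 (-3.96), Bmp7 (-2.45) and Bambi (-2.21). Of 19 Wnt genes 9 fell (1 up and 14 down adjusted over the list alone; 2.74e-05), with Tcf7 (-1.85), Wnt7b (-1.66), Lef1 (-1.12) and Sp5 (-0.74). Of 12 retinoic acid genes 5 fell and 1 rose (6 and 1 adjusted over the list alone; 0.000934), with Crabp2 (-3.94), Rdh10 (-1.92), Aldh1a3 (-0.69) and, chosen after their values were seen, Crabp1 (-1.89) and Stra6 (1.16). These 10 neuronal, epithelial and signalling groups also passed with an estimated correlation, with adjusted p from 0.00237 to 0.0329.

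With the preset correlation alone, 17 of 24 G1/S genes fell (20 adjusted over the list alone; camera adjusted p = 5.2e-10; adjusted p = 0.101 with an estimated correlation), with Ccne1 (-2.77), Gins2 (-2.71), Mcm6 (-2.24) and Rrm2 (-2.04). Of 24 G2/M genes 3 fell, also adjusted over the list alone (0.000803; adjusted p = 0.426 with an estimated correlation), Bub1b (-1.97, 5 of 6 plates), Ccnb1 (-1.57, 5 of 6) and Birc5 (-1.46). Of 8 Hedgehog genes 4 fell, also adjusted over the list alone (0.00608; adjusted p = 0.0707 with an estimated correlation), Gli3 (-1.94), Gas1 (-1.84), Smo (-1.68) and Cdon (-1.37). Of 21 otic patterning genes 9 fell and 3 rose (10 and 3 adjusted over the list alone; 0.0115; adjusted p = 0.0707 with an estimated correlation). Tbx2 (-3.49), Gbx2 (-2.97) and Tbx1 (-2.58) were among those that fell, and Six4 (1.47), chosen after its values were seen, among those that rose. Of 7 neurotrophin genes 3 rose (3 up and 2 down adjusted over the list alone; 0.0115, median -0.03, mean 1.39, test upward; adjusted p = 0.115 with an estimated correlation), with Gfra1 (2.59) and Ntrk2 (2.46).

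The other groups did not pass. Of 17 Notch genes 4 rose and 2 fell (4 and 3 adjusted over the list alone; camera adjusted p = 0.122), Mfng (4.17), Hes6 (3.76), Dll3 (3.44) and Hes1 (-3.88) and, chosen after their values were seen, Rfng (1.63) and Jag1 (-1.77). Of 14 epithelial-mesenchymal transition genes 4 rose and 3 fell (4 each adjusted over the list alone; 0.918), with Zeb2 (3.71), Vim (3.12), Sox9 (-4.63) and Sparc (-4.16), and, chosen after their values were seen, Zeb1 (2.51), the cadherin Cdh2 (1.72) and Fn1 (-2.18). Of 17 FGF genes 2 rose and 6 fell (3 and 8 adjusted over the list alone; 0.245), with Fgf10 (3.34), Fgf3 (1.06, 5 of 6 plates), Fgf9 (-2.54) and Fgfr2 (-2.45). Of 14 glycolysis genes 1 rose and 3 fell (1 and 6 adjusted over the list alone; 0.311), Gpi1 (1.22), Gapdh (-1.01), Pgk1 (-0.86) and Aldoc (-0.74). Fos (-2.15) alone fell among immediate early genes, also adjusted over the list alone (0.428), and no Hox gene passed, also adjusted over the list alone (0.551; Hoxb3 0.08, adjusted p = 0.869, 1 of 6 plates).

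After the correction for transfer the calls of Ccnb1 (-1.62, adjusted p = 0.0606), Pgk1 (-1.06, 0.0519) and Aldoc (-0.68, 0.063) ended, and in cells without a source well the median of the G2/M list was -0.02 and camera pointed upward (adjusted p = 0.939). In those cells 35 of 75 calls of named genes ended (median ratio 0.82), against 8 of 78 with the log2 of the mean FPKM, and with fry the G2/M list lost its call. Aldoc lost its call in 10 settings and Birc5 and Rb1 in 6 each. The count ran from 352 in cells without a source well to 2321 with classes weighted by their number of cells.

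The comparison of mesenchyme-like with otic epithelium-like cells sets the lower epithelial genes of early neuroblast-like cells beside those of a tissue that is not epithelial. Mmp2 (ENSMUSG00000031740, chromosome 8, 92827291 to 92853420), a matrix metalloproteinase, was higher by 4.98 (SE 0.46, n = 2, adjusted p = 1.02e-06), and Pcolce (ENSMUSG00000029718, chromosome 5, 137605103 to 137613784), an enhancer of collagen processing, by 4.80 (SE 0.32, n = 2, adjusted p = 2.64e-08). Cldn6 differed by -6.65 (SE 0.48, n = 2, adjusted p = 6.33e-08). Gap43 (4.69), Mogat2 (4.61), the chemokine Cxcl12 (4.44) and the adhesion gene Vcam1 (4.16) were also higher, and Wfdc2 (-6.13), Krt18 (-5.92), Spint2 (-5.75), Cldn7 (-5.53) and Ap1m2 (-5.51) lower. Of the 10168 genes 685 differed, 270 higher and 415 lower.

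Of 30 epithelial genes 20 fell and none rose (26 adjusted over the list alone; camera adjusted p = 1.1e-35), with Krt8 (-4.81). Of 21 otic patterning genes 12 fell and none rose (16 adjusted over the list alone; 4.23e-15), with Tbx2 (-3.70), Tbx1 (-2.68), Gbx2 (-2.59) and Gata3 (-2.49). Both groups passed with an estimated correlation (adjusted p = 0.00123 each). Lower than in the epithelium in both mesenchyme-like and early neuroblast-like cells were 244 genes. In 100 simulations of unchanged classes that share the epithelial means, lists of these sizes shared a mean of 100.3 genes (highest 118). Higher in both were 11, below the simulated mean of 37 (highest 50). These simulations too held no class effect, so they do not give the overlap expected of classes that differ.

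With the preset correlation alone, 6 of 24 G2/M genes rose (12 adjusted over the list alone; camera adjusted p = 1.32e-08; adjusted p = 0.342 with an estimated correlation), with the mitotic genes Cdk1 (2.09), Top2a (2.08), Aurkb (1.95) and Birc5 (1.82). Of 24 G1/S genes 1 rose, also adjusted over the list alone (0.0133; adjusted p = 0.607 with an estimated correlation), Rrm2 (1.35, 5 of 6 plates). Of 15 BMP genes 4 fell (6 adjusted over the list alone; 8.91e-05; adjusted p = 0.177 with an estimated correlation), Id4 (-3.41), Bmp7 (-2.22), Msx1 (-1.89, 5 of 6 plates) and Bambi (-1.81). Of 17 basement membrane genes 5 fell and 2 rose (6 and 2 adjusted over the list alone; 0.00262; adjusted p = 0.0546 with an estimated correlation), with Col18a1 (-3.34), Fras1 (-1.44), Frem2 (-1.11) and Nid1 (1.62, 5 of 6 plates), and, chosen after their values were seen, Itga6 (-1.70), Lama5 (-0.86) and Nid2 (1.23). Of 19 Wnt genes 4 fell and 1 rose (5 and 1 adjusted over the list alone; 0.0291, downward; adjusted p = 0.321 with an estimated correlation), with Wnt7b (-1.71), Dkk1 (-0.89, 5 of 6 plates), Sp5 (-0.72) and Fzd2 (1.90), and, chosen after its values were seen, Tcf7 (-1.10).

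Among groups that did not pass, 3 of 14 epithelial-mesenchymal transition genes rose and 3 fell (4 each adjusted over the list alone; camera adjusted p = 0.544), Mmp2, the mesenchymal cadherin Cdh11 (3.2), Snai2 (1.4, 5 of 6 plates) and Sparc (-3.03, 5 of 6). Chosen after their values were seen, the others were Sox9 (-1.78) and Cdh2 (-1.59). Of 12 retinoic acid genes 2 rose and 1 fell (2 and 4 adjusted over the list alone; 0.544, median -0.15, mean 0.19, test downward), the retinoic acid-degrading Cyp26a1 (3.35), Crabp1 (2.68, 5 of 6 plates) and Aldh1a3 (-0.70). Of 17 FGF genes 2 rose and 2 fell (2 and 4 adjusted over the list alone; 0.256), Dusp6 (1.76, 5 of 6 plates), Fgfr1 (1.56), Fgf9 (-2.71) and Etv5 (-1.44). Of 19 cytoskeleton genes 3 rose and 1 fell, also adjusted over the list alone (0.424), Gap43, Basp1 (2.76), Crmp1 (2.42) and Dpysl3 (-1.80, 5 of 6 plates). Of 5 Hox genes Hoxa2 rose (2.77, with 4.38 and 1.17 in the replicates, 5 of 6 plates; 2 adjusted over the list alone; list 0.0641).

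Of 9 cell cycle exit genes 2 fell, also adjusted over the list alone (camera adjusted p = 0.119), Cdkn1c (-1.54, 5 of 6 plates) and, chosen after its values were seen, Cdkn1a (-1.38). Of 7 neurotrophin genes 1 fell and 1 rose (2 down and 1 up adjusted over the list alone; 0.424), Bdnf (-2.23) and, chosen after its values were seen, Ntf3 (1.41). Of 24 axon guidance genes also 1 fell and 1 rose (1 down and 2 up adjusted over the list alone; 0.424), Epha7 (-1.93, 5 of 6 plates) and, chosen after its values were seen, Plxna2 (1.53). Jag1 (-2.27) fell in the Notch list, also adjusted over the list alone (0.267), and Cdon (-1.19) in the Hedgehog list (0.586, median 0.16, mean -0.10, test downward; 2 adjusted over the list alone). Hspa8 was called among immediate early and heat shock genes (0.37, adjusted p = 0.0193, 5 of 6 plates; list 0.641; 1 up and 1 down adjusted over the list alone). No gene passed, also adjusted over the list alone, among the lists for migration (0.544; Sema6a -1.34, adjusted p = 0.0806, 5 of 6 plates), synaptic vesicles (0.858) and glycolysis (0.641, median 0.03, mean -0.15, test downward; Aldoc -0.74, adjusted p = 0.0724, 6 of 6).

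Mesenchyme-like cells numbered 15 and 8 in the replicates, and after the correction for transfer the calls of Top2a (1.39, adjusted p = 0.116), Fgfr1 (1.34, 0.0704) and Hspa8 (-0.27, 0.723) ended, the last with its direction turned. The Wnt list lost its call there too (camera adjusted p = 0.0685), and the Wnt, G1/S and G2/M lists lost theirs with fry. Without the replicate block the calls of Msx1 (adjusted p = 0.0665) and Hspa8 (0.169) ended, and with the log2 of the mean FPKM 18 of 54 calls of named genes ended. Dusp6, Etv5 and Hspa8 lost their calls in 6 settings each, and Fgfr1 and Msx1 in 5 each. The count was 405 with the filter at 20% of cells and 417 with at least 4000 genes per cell, and with the log2 of the mean FPKM 16.8% of 501 genes were higher, against 39.4% of 685.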

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

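The tests of transcripts shared between wells were chosen after the sharing had been seen, and the tests of epithelial transcripts in early neuroblast-like cells were written before their results were seen, except those against surface ectoderm-like cells, in each replicate, by plate, in cells without a source well and at a halved FPKM. Across 281 groups of 6 plates, 13 held a plate that stood far from the other plates, against 14.1 expected by chance.

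Cells in neighbouring rows of a plate column shared transcripts beyond their class. Residual correlations had a median of 0.106 over 372 pairs in neighbouring rows, against -0.014 for rows further apart and -0.012 for neighbouring columns, and 19 pairs of row positions were linked in both replicates, where 0.7 are expected by chance. Liquid carried between touching wells is argued against, for those pairs, by 2 linked pairs that lay on different plates. Within plates, 17 of 17 links ran from a later to an earlier row (exact binomial test, two-sided, p = 1.5e-05 against an equal split). These links join up in runs of successive rows and are not independent, so this p overstates the evidence. It speaks against liquid carried equally both ways, but not against liquid carried in 1 direction. A well with 2 cells is argued against by the cells with both Xist and a Y-linked transcript, 53 of 337 with a source well and 1 of 154 without (Fisher's exact test, two-sided, p = 1.3e-08). The 19 pairs that recur on other plates are in line with a tagged primer or index shared between row positions at the library step, and no biological explanation was tested because the row of a well is no group of the study.

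Epithelial transcripts stood in part of the early neuroblast-like cells: after the correction 14 of 41 held Epcam, and the cells held a mean of 4.7 of 30 epithelial junction and keratin genes, against 2.5 in neural tube progenitor-like and 15.9 in otic epithelium-like cells. Cluster 7 held 5.2, and Epcam in 30.2% of its cells, so the residue is not particular to early neuroblast-like cells. When corrected values were clustered again, 35 of the 41 early neuroblast-like cells kept their class. Of the others, 3 fell in the otic epithelium-like and 3 in the neural tube progenitor-like class. On the most variable genes 22 kept it and 5 fell in the otic epithelium-like class. Whether these cells hold the epithelial transcripts was not tested, so an uncertain class stays open. Transfer between wells as the whole cause is argued against by the difference from neural tube progenitor-like cells that stayed after the correction. It was 2.6 genes as the mean of the replicates (permutation of cells within replicates, one-sided, p = 1e-05, the smallest these permutations can give), 3.8 in replicate 1 (p = 0.00014) and 1.4 in replicate 2 (p = 0.0055), and ran from 0.44 to 6.42 on the 6 plates. The highest was plate 2, without which it was 1.4 (p = 0.0046), and 1.3 in replicate 1 (p = 0.082). These tests take cells as the units, and the size of the difference is uncertain. In cells without a source well it was 1.4 (p = 0.067), and the correction itself took the mean from 7.4 to 4.7, so transfer may account for part. Of the 14 early neuroblast-like cells with no linked source well among the cells kept, 6 held Epcam as deposited. A second, otic epithelium-like cell in the well is argued against, for the 14 cells as a set, by otic patterning genes, with a mean of 6.6 in these cells and 8.6 in otic epithelium-like cells (permutation test, one-sided, p = 0.0071; 0.061 and 0.033 in the replicates alone, and 0.018 against cells with their FPKM halved). For single cells it stays open. Of the 14 cells, 3 held at least as many of these genes as the epithelial mean, but otic epithelium-like cells also lie below their own mean. The 6.6 of the set lies between the 5.2 of early neuroblast-like cells without Epcam and the 8.6, so some of the 14 may hold a second cell. A second, surface ectoderm-like cell is argued against, also for the set, by 9.5 fewer epithelial genes than in surface ectoderm-like cells (p = 1e-05). An earlier point of the lineage, the biological explanation, may account for the cells and stays open: Neurog1 was found in 8 of 14 cells with Epcam and 12 of 27 without (Fisher's exact test, two-sided, p = 0.52), and neuron genes numbered 9.3 and 11 (permutation test, two-sided, p = 0.076). Without the cells of endothelial or macrophage markers, a setting chosen after seeing the data, the difference from neural tube progenitor-like cells was 2.55 (p = 3e-05) and that in otic patterning genes -1.95 (p = 0.00745).

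Neural crest or glial precursor-like cells made up 3.8% of plate 3 (3 of 78 cells, 95% interval 0.8 to 10.8), where the other plates held 0 or 1 cell each and the intervals overlap. In early neuroblast-like minus otic epithelium-like cells, plate 2 stood apart with log2 differences of -2.39 for Krt18, -2.84 for Cldn6 and -0.29 for Astn1. On that plate 6 of the 7 early neuroblast-like cells had a source well, and these 7 cells held a mean of 8.6 epithelial genes after the correction, against 3.3 to 4.3 on the other plates. In neuron-like minus otic epithelium-like cells, the plates that stood apart were plate 3 for Zeb2 (3.94), plate 1 for Rb1 (3.65), and plate 5 for Hoxb3 (0.49). In mesenchyme-like minus otic epithelium-like cells, plate 6, with 2 mesenchyme-like cells, stood apart for Sparc (2.02), Rrm2 (-1.36), Cdkn1c (1.0) and Msx1 (1.1). In cluster 7 minus neuron-like cells, plate 4 stood apart for Prnp (1.23) and plate 3 for 3110039M20Rik (-0.58).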

How the results depend on the processing

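The settings that correct or avoid transfer between wells, the pooling of clusters 5 and 7, the removal of cells with endothelial or macrophage markers, and all values of cluster 7 minus neuron-like cells were chosen after seeing the data. Counts are given for early neuroblast-like minus otic epithelium-like (579), neuron-like minus early neuroblast-like (493), neuron-like minus otic epithelium-like (1449), mesenchyme-like minus otic epithelium-like (685), genes highest in early neuroblast-like cells (23) and cluster 7 minus neuron-like cells (240). Of the counts and shares under alternatives, 128 stayed near the value reported and 47 moved, and of the values of named genes 4924 kept their direction and side of the threshold, 389 lost and 51 gained a call, and 3 changed sign. Each called gene kept its direction in each replicate alone, where no test is left, which is expected of genes called from these replicates and adds no support. The counts of called genes that kept their direction there are among the 128. Without the replicate block the counts were 541, 433, 1346, 628, 23 and 219, and 46 lists were called, as with it.

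With the log2 of the mean FPKM the counts were 375, 298, 13 and 139 in the first, the second, the fifth and the sixth comparison. With classes weighted by cells they were 935 and 2321 in the first and the third. With no filter the fifth was 36, and with the filter at 20% of cells the fourth, the fifth and the sixth were 405, 10 and 122, where fewer genes were tested. With at least 4000 genes per cell, which left 384 cells, the first, the second, the fourth and the sixth were 314, 319, 417 and 149. Clustered on the most variable genes, the second, the third, the fifth and the sixth were 1428, 2311, 93 and 564, where the early neuroblast-like class held 22 cells that are early neuroblast-like and 20 that are neuron-like by markers. At resolution 0.5 the sixth was 373, and the first, the second and the fifth have no value because early neuroblast-like and neuron-like cells formed 1 class. In cells without a source well, 154 in number, the counts were 145, 39, 352, 5 and 54, with no value for the fourth because mesenchyme-like cells were too few. With corrected values clustered again, the second was 712 and the fifth 38. Where no construction is named, the cause was not tested.

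Camera called 46 lists with the preset and 23 with an estimated correlation, and fry called 50. The 3 values that changed sign were these: Dusp1 between neuron-like and early neuroblast-like cells was -0.03 in cells without a source well, and Hspa8 in mesenchyme-like cells was -0.27 with corrected values and -0.28 when these were clustered again. The cause was not tested.

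Shares of cells moved with the clustering. On the most variable genes they were 6.7% for cluster 7, 5.7% for neuron-like, 0.0% for neural crest-like, 25.9% for neural tube-like and 29.7% for otic epithelium-like cells. At resolution 0.5 they were 0.0% for cluster 5, early neuroblast-like and neural crest-like cells, 12.8% for cluster 7, 18.7% for neuron-like, 26.1% for neural tube-like and 29.1% for otic epithelium-like cells. With at least 4000 genes they were 6.2% for cluster 5, 12% for neuron-like, 16.9% for neural tube-like and 32.8% for otic epithelium-like cells. With corrected values clustered again they were 5.1% for cluster 5, 7.8% for cluster 7, 8.4% for neuron-like, 0.0% for neural crest-like and 26.7% for neural tube-like cells. No depth in reads is known, so a value of 0 is read as not detected.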

Other observations

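The comparison of cluster 7 with neuron-like cells was chosen after the clusters were seen. Of 10168 genes 240 differed between neuron-like cells and cluster 7, 119 higher and 121 lower in cluster 7. Tlx2, a homeobox gene of peripheral neurons, was higher by 5.51 (SE 0.35, n = 2 replicates, adjusted p = 2.33e-08), with Tppp3 (log2 difference 5.03), the retinoic acid-binding Crabp1 (5.00), the prion protein gene Prnp (4.71), the nicotinic receptor subunit Chrna3 (4.11) and the secretin gene Sct (3.90), each in 2 of 2 replicates. The myelin and neuronal membrane gene Gpm6b (-4.44, adjusted p = 2.11e-06), the growth arrest gene Rprm (-3.97), the ligand Fgf10 (-3.68), 3110039M20Rik (-3.20) and Pde4dip (-3.08) were lower, each in 2 of 2 replicates. In cells without a source well 4 of 11 of these calls ended, those of Sct (3.08, adjusted p = 0.161), Gpm6b (-2.4, 0.319), 3110039M20Rik (-2.14, 0.131) and Pde4dip (-3.08, 0.0919). With the log2 of the mean FPKM 3 ended, those of Crabp1 (3.45, 0.0875), Chrna3 (3.11, 0.0709) and 3110039M20Rik (-3.16, 0.0879). Of the gene lists, camera with the preset correlation called epithelial genes (3 up, adjusted p = 0.000121), Hox genes (1 of 5 up, 3 adjusted over the list alone, 0.000115), G2/M genes (1 down, 9 adjusted over the list alone, 6.13e-10) and synaptic genes (1 up and 4 down, 0.0149), and none of these passed with an estimated correlation (adjusted p = 0.122, 0.121, 0.249 and 0.122). Against otic epithelium-like cells, cluster 7 had 606 genes higher and 907 lower, led by the neurofilament genes Nefm (8.91) and Nefl (8.46).

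The further classes were each compared with otic epithelium-like cells, over 10168 genes and with 2 of 2 replicates in the direction given. Cluster 5, in which 57.8% of cells held the neural tube gene Pax6 and 97.8% the neuronal tubulin gene Tubb3 as deposited, and 45.5% and 72.7% after the correction for transfer, had 366 genes higher and 1269 lower, with Crabp1 (6.0), Tagln3 (5.24), the stress kinase Plk3 (5.24), the creatine kinase Ckb (4.84), Crmp1 (4.75) and the Notch ligand Dll3 (4.65) highest. Neural tube progenitor-like cells had 149 higher and 477 lower, with the axonal transport gene Fez1 (5.33), the Notch target Hes5 (5.23), Ckb (5.14), the ciliary transcription factor Rfx4 (4.65), the growth factor receptor Fgfr3 (4.38) and Pou3f2 (3.90). Surface ectoderm-like cells had 210 higher and 249 lower, with the annexin Anxa2 (6.0), the BMP antagonist Sostdc1 (5.57), the keratin Krt7 (5.13), the glucose transporter Slc2a3 (5.09), Igfbp5 (4.11) and Cnn2 (4.02), and with Tbx2 (-4.93) and Car2 (-4.94) lowest. The epithelial genes Cldn6 and Krt18 were lower in cluster 5 (-7.32 and -7.09), in neural tube progenitor-like cells (-6.75 and -6.63) and in cluster 7 (-6.20 and -4.98).

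The 10 housekeeping genes were above 0 in all 491 cells, no 2 columns of the table were identical, and the highest correlation between 2 cells was 0.968, against a median of 0.6.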
